A study of Homo sapiens with 24 samples.

How the data were processed

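RNA sequencing libraries were made from 4 human breast cancer cell lines, with 3 biological replicates in each of 8 groups. BT549 and MCF7 cells had been stably transfected with an empty expression vector or the same vector carrying Lbh, by nucleofection in BT549 and by lipofection in MCF7. MDA-MB-231 and HCC1395 cells had been transfected with a pool of LBH siRNA or a scrambled control siRNA at 2 nM for 72 hours. Per the labels, total RNA was isolated and libraries were enriched for mRNA. The labels do not state the species of the Lbh insert.

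The authors deposited raw counts per Ensembl gene, 1 column per library, with no normalization. The processing notes name the genome build hg19, STAR 2.5.0, featureCounts 1.5.0 and edgeR without a version, and do not state the annotation release or the strand setting. The table held 48162 genes, of which 45650 identifiers had GRCh37 coordinates and 34314 a gene symbol. All 24 columns were used. The names of 18 columns point to a line, and the other 6 columns were assigned to MCF7 from their initial letter and by elimination. ESR1, the estrogen receptor gene, was looked at in these columns only after the assignment. It stood between 243 and 276 CPM there and at no more than 2.56 CPM in all other libraries. Total counts per library ranged from 14181372 to 23636019.

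Each line was analysed with its own 6 libraries in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), scaled by the trimmed mean of M values (TMM), and tested with the quasi-likelihood F test, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a line, and genes under 0.05 were called. The SE of a log2 fold change was its size divided by the square root of F. CPM values used TMM factors within the line, except those of LBH, which used factors over all 24 libraries so that lines share 1 scale. For a group with 3 or fewer LBH counts, 3 counts over the group set the floor. A difference between 2 lines with the same kind of manipulation was tested as an interaction over their 12 libraries, as the effect in the line named first minus that in the other.

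Before the data were examined, 30 gene lists of pathways, cell states and markers of other cell types were fixed. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a line, then with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took LBH, and in each line the 8 called genes with the largest rise and the 8 with the largest fall, at 5 CPM or more in the higher group and with groups that did not overlap. It also took up to 3 called members per list, the first 10 genes called in at least 3 lines with 1 direction relative to the labelled LBH status, and up to 5 genes per direction shared by a pair of lines. Annotated pseudogenes and symbols of the forms used for clones and for antisense, long intergenic and small RNAs were passed over; other noncoding genes were not. Of the MCF7 falls that the rule took, 1 gene of a class whose levels are not printed was left out of the text. Overlaps between lines were counted among genes tested in both, beside the number expected from independent draws.

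Alternatives fixed before the data were examined were DESeq2 size factors, no low count filter, the DESeq2 1.42.0 Wald test, 1 model of all 24 libraries, the replicate number as a block, an absolute log2 fold change of at least 1, the other set tests, and leaving out each library in turn. Total count scaling, offsets for exon length and for GC content, removal of the median change of 10 Mb windows, and alternatives for list differences were added after the data were seen. Where 1 library was left out, the remaining 2 of its group were assumed to vary like the other group. All splits of a line's 6 libraries into 3 and 3, 10 in number, and 100 drawn splits per pair of lines were refitted. The steps were tested on simulated data with the depths of these libraries, where edgeR recovered 70% to 92% of genes given a log2 change of 1, and 3.6% to 8.2% of all calls were false. The simulated counts were drawn independently per gene, with few changed genes and no outlying library or block-wise shift. These rates therefore need not hold for the real comparisons.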

Results

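Transcript levels were measured by RNA sequencing in 4 human breast cancer cell lines in which the level of LBH, a transcription cofactor first described in limb bud and heart development, was manipulated. BT549, MDA-MB-231 and HCC1395 are lines of the triple negative type, and MCF7 is a luminal, estrogen receptor positive line. BT549 and MCF7 cells carried either an empty expression vector or a vector for LBH overexpression after stable transfection. MDA-MB-231 and HCC1395 cells received 2 nM of a pool of LBH siRNA or a control siRNA for 72 hours. The 24 libraries formed 8 groups of 3 biological replicates, and each line had its own control group. Total counts per library ranged from 14181372 to 23636019. Normalised levels are CPM (counts scaled to the effective library size), given as mean ± SD over 3 replicates, and changes are log2 fold changes against the control group of the same line. "Rose" and "fell" are used of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test.

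LBH reads fell in the LBH siRNA libraries of MDA-MB-231, were lower without passing the test in those of HCC1395, and were not higher in either set of libraries labelled LBH overexpression. LBH (ENSG00000213626) is a protein-coding gene on the plus strand of chromosome 2, from 30454400 to 30546596 in GRCh37. In MDA-MB-231, the control siRNA libraries held 17.7, 17.4 and 18.1 CPM and the LBH siRNA libraries 0.998, 1.52 and 1.83 CPM. The group mean dropped from 17.7 ± 0.341 to 1.45 ± 0.420 CPM (SD, n = 3), which left 8.2% of the control level (log2 fold change -3.62 ± 0.21 SE, adjusted p = 4.06e-12). In HCC1395, the control siRNA libraries held 9.14, 5.00 and 11.9 CPM and the LBH siRNA libraries 2.17, 2.15 and 2.70 CPM. The group means were 8.67 ± 3.45 and 2.34 ± 0.308 CPM, which left 26.8% of the control level (log2 fold change -1.90 ± 0.31 SE), but the adjusted p was 0.0530 in edgeR. DESeq2 gave LBH in HCC1395 an adjusted p of 1.41e-05. EdgeR called it with the replicate number as a block (log2 fold change -1.84, adjusted p = 6.38e-06), all 24 libraries in 1 model (adjusted p = 3.29e-05), no low count filter (5.22e-12) and exon length offsets (0.0199). It also called LBH without control replicate 2 (log2 fold change -2.16, adjusted p = 0.0347) or without control replicate 3 (-1.61, adjusted p = 0.00251). It did not call LBH without control replicate 1 (adjusted p = 0.411), without LBH siRNA replicate 1, 2 or 3 (0.256, 0.430 and 0.253), or with total count scaling (0.136).

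In BT549, LBH reads went against the label. The vector libraries held 2.76, 2.69 and 2.58 CPM and the libraries labelled LBH overexpression 1.37, 0.916 and 0.974 CPM. The group means were 2.68 ± 0.0927 and 1.09 ± 0.248 CPM (SD, n = 3), so LBH fell to 40.8% of the vector level (log2 fold change -1.29 ± 0.24 SE, adjusted p = 0.00649). In MCF7, 1 LBH read was counted over the 3 vector libraries and 1 over the 3 libraries labelled LBH overexpression. Both are below a floor of 3 counts over the group, which corresponds to 0.0540 CPM for vector and 0.0550 CPM for the labelled libraries, so no LBH difference was detectable at this depth and the gene was not tested. The 2 overexpression comparisons therefore rest on the labels. The floors cover counting error only.

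**Figure D1:**
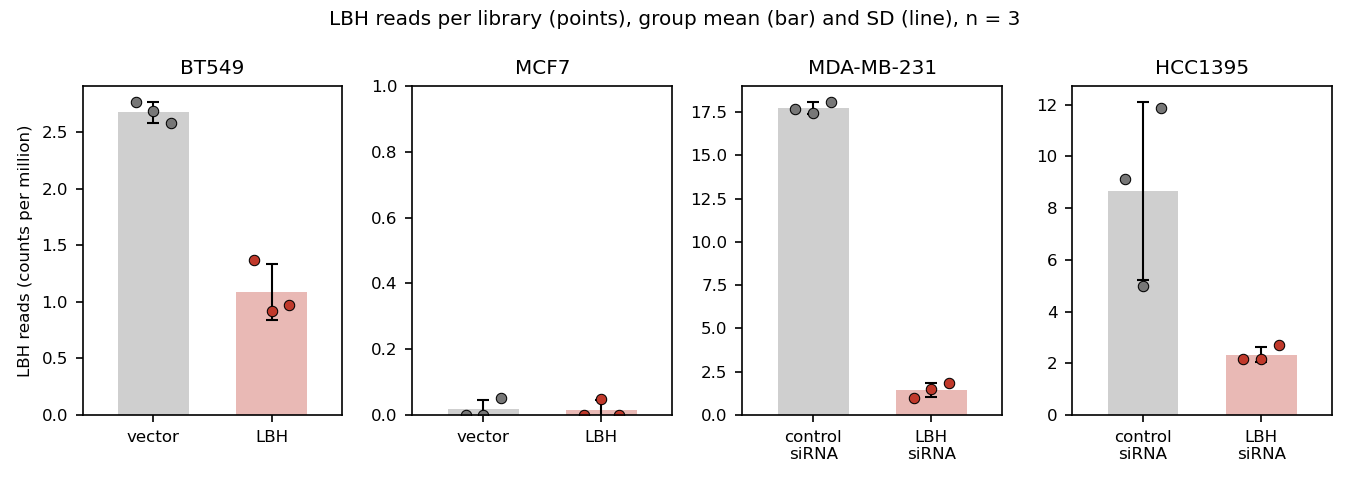
LBH reads in CPM for each library (points), with group mean (bar) and SD (line, n = 3) for the control and manipulated groups of the 4 lines, each panel with its own vertical axis starting at 0. LBH dropped from 17.7 to 1.45 CPM after LBH siRNA in MDA-MB-231, was lower by the mean in HCC1395 and BT549, and stayed at 1 count per group in MCF7.

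The BT549 comparison asked which genes differ between libraries labelled LBH overexpression and vector libraries in a triple negative line. The interferon-stimulated genes MX1, IFI6 and IFIT3 and the lipid synthesis genes FADS2, SREBF1 and SCD rose, while the hypoxia and glycolysis genes NDRG1, SLC2A1 and PDK1, the collagen VI genes COL6A1 and COL6A2 and the protease gene MMP2 fell. MX1, an interferon-induced antiviral GTPase, rose from 1.35 ± 0.385 to 8.81 ± 4.71 CPM (SD, n = 3; log2 fold change 2.66 ± 0.37 SE, adjusted p = 0.000766). THBS2, a secreted matrix protein that inhibits blood vessel growth, rose from 67.8 ± 3.23 to 216 ± 21.4 CPM (log2 fold change 1.68 ± 0.07 SE, adjusted p = 4.56e-08). MMP2, a secreted gelatinase, fell from 54.3 ± 3.96 to 19.8 ± 0.971 CPM (log2 fold change -1.45 ± 0.08 SE, adjusted p = 1.77e-07). Some of the falls were neighbours: MMP2, LPCAT2 (log2 fold change -1.48) and GNAO1 (-2.33) start at 55423612, 55542984 and 56225302 on chromosome 16. COL6A1 and COL6A2 start at 47401684 and 47518026 on chromosome 21. Whether such close genes moved as a block between the transfectant populations was not tested. The changes were mostly modest: of 14646 genes tested, 403 rose and 343 fell, and 92 of these 746 changed by at least 2-fold.

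Interferon-stimulated genes moved furthest as a list in BT549. Of 34 measured members, 20 rose, none fell and 14 did not pass, or 24 rose adjusted over the list alone. The list's camera adjusted p was 6.24e-29, but adjusted p = 0.129 with an estimated correlation. RSAD2 (log2 fold change 2.73), OAS2 (1.96), IFI6 (1.32), IFIT1 (1.29) and IFIT3 (1.24) were among the rises, at low levels for RSAD2 and OAS2, which had 1.33 and 1.31 CPM in the labelled libraries. Antigen presentation genes were called higher with 4 of 13 members rising and 9 not passing, also 4 adjusted over the list alone, and PSMB9, a subunit of the immunoproteasome, rose from 4.57 ± 1.30 to 8.05 ± 1.93 CPM. That list call (adjusted p = 0.0358) had adjusted p = 0.523 with an estimated correlation. It also ended without vector replicate 1 (adjusted p = 0.0767), vector replicate 2 (0.0593) or labelled replicate 2 (0.160), with exon length offsets (0.0623) and with DESeq2 test statistics (0.0538).

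Lipid synthesis genes were also called higher in BT549. Of 32 measured cholesterol and fatty acid synthesis genes, 7 rose, 1 fell and 24 did not pass, or 12 and 2 adjusted over the list alone (adjusted p = 1.19e-06; adjusted p = 0.134 with an estimated correlation). FADS2, a fatty acid desaturase, rose from 378 ± 13.8 to 531 ± 2.73 CPM, and SREBF1, a transcription factor of lipid synthesis, and SCD, the stearoyl-CoA desaturase, rose with log2 fold changes of 0.39 and 0.36. Nuclear-encoded oxidative phosphorylation genes shifted up by a median of 0.12, although edgeR called none of the 41 members, 10 had an unadjusted p under 0.05, all 10 higher, and DESeq2 called 1 (adjusted p = 0.000288; adjusted p = 0.608 with an estimated correlation). Without labelled replicate 2 that list's adjusted p was 0.0782.

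Hypoxia and glycolysis genes were lower in BT549. Of 31 measured members, 10 fell, none rose and 21 did not pass, or 17 fell adjusted over the list alone (adjusted p = 3.24e-16; adjusted p = 0.134 with an estimated correlation). SLC2A1, the main glucose importer of many cells, fell from 51.7 ± 2.00 to 28.2 ± 2.60 CPM (log2 fold change -0.87 ± 0.08 SE). PDK1, a kinase that inhibits pyruvate dehydrogenase, and NDRG1, a hypoxia-induced gene, fell with log2 fold changes of -0.70 and -1.02. Of 37 matrix protein genes, 4 rose, 11 fell and 22 did not pass, or 6 and 15 adjusted over the list alone (adjusted p = 4.96e-05; adjusted p = 0.523 with an estimated correlation). The collagen VI genes COL6A1 and COL6A2 fell from 996 ± 5.22 to 499 ± 11.2 CPM and from 634 ± 23.9 to 354 ± 17.8 CPM, and COL3A1 fell with a log2 fold change of -0.50, opposite to THBS2. Of 26 matrix proteases and inhibitors, 4 rose, 6 fell and 16 did not pass, or 5 and 11 adjusted over the list alone (adjusted p = 0.000568; adjusted p = 0.134 with an estimated correlation). SERPINE1, an inhibitor of plasminogen activators, rose (log2 fold change 0.75). TIMP3, a protease inhibitor, fell (-2.09) from 2.52 ± 1.56 to 0.573 ± 0.0694 CPM, a low level with uneven vector libraries. Beside these, 1 of 6 fibroblast and adipocyte markers rose in BT549, FAP (0.36), and 2 fell, COL3A1 and MFAP5 (-1.61, from 0.938 CPM).

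Immediate early genes, which respond within minutes to growth signals, were lower in BT549, with 7 of 30 falling, none rising and 23 not passing, or 8 falling adjusted over the list alone (adjusted p = 0.000866; adjusted p = 0.134 with an estimated correlation). NR4A2, SPRY4 and DUSP1 fell with log2 fold changes of -0.93, -0.47 and -0.37. Of 30 unfolded protein response and amino acid stress genes, 3 fell, none rose and 27 did not pass, or 9 fell adjusted over the list alone (adjusted p = 0.00209; adjusted p = 0.523 with an estimated correlation). PHGDH, the entry enzyme of serine synthesis, fell with a log2 fold change of -0.42 ± 0.06 SE. Outside the lists, ATP2B2, a calcium pump of the plasma membrane, rose 3.45-fold, and GNAO1, a G protein subunit, and IQGAP2, a scaffold protein, fell with log2 fold changes of -2.33 and -1.77. No BT549 list call held with an estimated correlation, where the smallest adjusted p was 0.129. With the preset correlation, splits that mixed the labels gave up to 8 list calls, against 9 for the real grouping. The gene count was 443, 398 or 402 without vector replicate 1, 2 or 3, 318 without labelled replicate 1 and 1362 without labelled replicate 3, and 273 with all 24 libraries in 1 model.

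The MCF7 comparison asked the same question in a luminal line. The collagen genes COL3A1 and COL5A1, the ligand genes TGFB1 and TGFB2 and the ribosomal protein genes RPL30 and RPL7A rose, and the luminal gene TFF1, the epithelial gene CDH1, HLA-C and the interferon-stimulated genes IFI6 and OAS3 fell. COL3A1, a fibrillar collagen, rose from 24.3 ± 1.28 to 208 ± 2.13 CPM (SD, n = 3; log2 fold change 3.10 ± 0.06 SE, adjusted p = 6.04e-11). CDH1, the epithelial adhesion protein E-cadherin, fell from 1094 ± 20.8 to 505 ± 4.25 CPM (log2 fold change -1.11 ± 0.05 SE, adjusted p = 2.98e-08). Of 15681 genes tested, 2945 rose and 2815 fell, and 853 of these 5760 changed by at least 2-fold. The rises with the largest folds included TCIM, SLFN11, SLCO2A1 and COL4A6, with log2 fold changes of 4.91, 4.12, 4.11 and 3.33, and the first 3 stood between 0.176 and 0.652 CPM in the vector libraries. Among the falls, GPC6, a cell-surface proteoglycan, went from 8.84 ± 0.871 to 0.912 ± 0.338 CPM, and FAT1, an atypical cadherin, from 17.1 ± 2.09 to 2.91 ± 0.380 CPM.

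Of 30 measured matrix protein genes in MCF7, 9 rose, 11 fell and 10 did not pass, or 10 and 12 adjusted over the list alone. Camera called the list higher (adjusted p = 0.0158; adjusted p = 0.194 with an estimated correlation), with a mean log2 fold change of 0.21 but a median of -0.14, and the call ended without labelled replicate 2 (adjusted p = 0.0601) and with all 24 libraries in 1 model (0.422). COL3A1 and COL5A1 (log2 fold change 2.20) were the largest rises, and COL17A1 rose at 2.26 CPM. Of 23 TGF-beta and BMP pathway genes, 11 rose, 4 fell and 8 did not pass, or 12 and 4 adjusted over the list alone (adjusted p = 1.26e-05; adjusted p = 0.166 with an estimated correlation). The ligands TGFB1 and TGFB2 rose from 20.7 ± 2.94 to 70.6 ± 1.78 CPM and from 17.2 ± 2.84 to 59.5 ± 2.07 CPM, and SERPINE1 rose from 0.303 ± 0.0196 to 3.50 ± 0.378 CPM. Of 18 angiogenic factors and inhibitors, 9 rose, 2 fell and 7 did not pass, or 12 and 2 adjusted over the list alone (adjusted p = 0.00628; adjusted p = 0.194 with an estimated correlation). EDN1, the vasoconstrictor endothelin, and EFNB2, an ephrin ligand, rose with log2 fold changes of 1.33 and 0.91. Markers of other cell types moved both ways beside these in MCF7. COL3A1, also on the fibroblast list, the endothelial marker VWF (log2 fold change 2.60, at 1.38 CPM) and the leukocyte marker CORO1A (1.40) rose, and ERG (-2.64, from 0.810 CPM) and LCP1 (-0.69) of the last 2 lists fell.

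NF-kB target genes were called higher in MCF7, with 8 of 13 measured members rising, none falling and 5 not passing, also 8 adjusted over the list alone (adjusted p = 0.00348; adjusted p = 0.329 with an estimated correlation). With all 24 libraries in 1 model that call ended (adjusted p = 0.0567). RELB, an NF-kB subunit, rose from 6.57 ± 0.399 to 19.0 ± 0.730 CPM and TNFAIP3, a feedback inhibitor, from 3.67 ± 0.478 to 8.63 ± 1.16 CPM. Of 41 cytosolic ribosomal protein genes, 36 rose, none fell and 5 did not pass, also 36 adjusted over the list alone, with a median of 0.34 (adjusted p = 1.56e-09; adjusted p = 0.331 with an estimated correlation). RPL30 and RPL7A rose with log2 fold changes of 0.86 and 0.56, and reads of these genes can be shared with processed pseudogenes.

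Of 31 luminal and estrogen receptor genes in MCF7, 4 rose, 14 fell and 13 did not pass, or 4 and 16 adjusted over the list alone (adjusted p = 6.83e-07; adjusted p = 0.180 with an estimated correlation). TFF1, an estrogen-induced secreted peptide, fell with a log2 fold change of -1.37 ± 0.06 SE (adjusted p = 4.53e-08), while CXCL12, a chemokine also on that list, rose (log2 fold change 1.43). Of 33 epithelial genes, 2 rose, 15 fell and 16 did not pass, the same counts adjusted over the list alone (adjusted p = 0.000121; adjusted p = 0.302 with an estimated correlation). DSC2, a desmosomal cadherin, fell (log2 fold change -1.25) beside CDH1, and CLDN1, a tight junction protein, rose (1.48). Of 28 p53 targets, 4 rose, 10 fell and 14 did not pass, also 4 and 10 adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.329 with an estimated correlation), and the call ended without vector replicate 2 (adjusted p = 0.0558). MDM2, the p53 ubiquitin ligase, fell from 167 ± 25.7 to 99.8 ± 3.39 CPM.

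Antigen presentation genes were called lower in MCF7, with 1 of 17 measured members rising, 10 falling and 6 not passing, or 2 and 10 adjusted over the list alone (adjusted p = 0.00202; adjusted p = 0.180 with an estimated correlation). HLA-C fell from 28.3 ± 0.805 to 11.5 ± 0.650 CPM, although reads of HLA genes can be shared among relatives. Of 28 interferon-stimulated genes, 3 rose, 11 fell and 14 did not pass, or 3 and 12 adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.329 with an estimated correlation). IFI6 and OAS3 fell with log2 fold changes of -1.60 and -1.39. Of 30 hypoxia and glycolysis genes, 2 rose, 17 fell and 11 did not pass, or 2 and 18 adjusted over the list alone (adjusted p = 0.000121; adjusted p = 0.329 with an estimated correlation). NDRG1 fell from 74.9 ± 1.70 to 20.5 ± 0.993 CPM, and EGLN3, an oxygen-sensing hydroxylase, rose (log2 fold change 1.20). No MCF7 list call held with an estimated correlation, where the smallest adjusted p was 0.166. Splits that mixed the labels gave up to 8 list calls with the preset correlation, against 11 for the real grouping. The gene count was 3682 with all 24 libraries in 1 model, and neighbouring genes moved together along several chromosomes, with 15 windows of 10 Mb beyond the level that permuted gene positions gave.

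The MDA-MB-231 comparison asked which genes differ between LBH siRNA and control siRNA libraries in a triple negative line. In neither knockdown line was another LBH siRNA used, so effects of LBH loss cannot be told apart from other effects of the siRNA pool. The cytokine genes IL6, CXCL1 and CXCL8, the matrix genes FBN1 and COL17A1 and the mitosis genes CDK1 and KIF4A rose, and the lipid synthesis genes SCD, INSIG1 and FADS2 and the hypoxia gene CA9 fell. IL6, a cytokine, rose from 0.992 ± 0.158 to 17.0 ± 1.01 CPM (SD, n = 3; log2 fold change 4.08 ± 0.20 SE, adjusted p = 1.84e-13). The complement component C3 rose from 4.84 ± 0.768 to 85.6 ± 5.81 CPM (log2 fold change 4.15 ± 0.12 SE, adjusted p = 2.67e-17). SCD fell from 386 ± 19.7 to 167 ± 30.2 CPM (log2 fold change -1.21 ± 0.10 SE, adjusted p = 1.81e-09). Of 14817 genes tested, 2115 rose and 1973 fell, and of these 4088, 500 rose and 173 fell by at least 2-fold.

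NF-kB target cytokines and inflammation genes changed most as a list in MDA-MB-231. Of 23 measured members, 19 rose, none fell and 4 did not pass, or 20 rose adjusted over the list alone. The median log2 fold change was 1.68 (adjusted p = 3.63e-45), and the call held with an estimated correlation (adjusted p = 0.00869). CXCL1 and CXCL8, chemokines that attract neutrophils, rose from 0.599 ± 0.167 to 10.4 ± 2.53 CPM and from 1.74 ± 0.221 to 23.0 ± 1.06 CPM, and IL1B rose from 0.146 ± 0.0789 to 2.69 ± 1.20 CPM. Of 39 interferon-stimulated genes, 21 rose, 1 fell and 17 did not pass, or 23 and 3 adjusted over the list alone (adjusted p = 1.94e-07; adjusted p = 0.0307 with an estimated correlation). RSAD2 and OASL rose with log2 fold changes of 1.35 and 1.02. Of 21 antigen presentation genes, 8 rose, 1 fell and 12 did not pass, or 8 and 2 adjusted over the list alone (adjusted p = 0.0378; adjusted p = 0.429 with an estimated correlation). TAP2 rose from 34.0 ± 1.64 to 64.7 ± 4.29 CPM, and the list call ended without control replicate 2 (adjusted p = 0.0763) or LBH siRNA replicate 1 (0.180).

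Matrix and growth factor lists were called higher in MDA-MB-231. Of 33 matrix protein genes, 18 rose, 4 fell and 11 did not pass, the same counts adjusted over the list alone (adjusted p = 3.91e-09; adjusted p = 0.0405 with an estimated correlation). FBN1, the microfibril protein fibrillin, rose from 14.7 ± 1.41 to 83.1 ± 13.3 CPM and COL17A1, a hemidesmosomal collagen, from 14.5 ± 1.40 to 71.7 ± 5.45 CPM. Of 22 growth factor ligands and receptors, 13 rose, 2 fell and 7 did not pass, or 13 and 3 adjusted over the list alone (adjusted p = 2.99e-05; adjusted p = 0.0451 with an estimated correlation). The EGF receptor ligands AREG and EREG rose with log2 fold changes of 1.79 and 1.27. Of 22 matrix proteases and inhibitors, 9 rose, 6 fell and 7 did not pass, also 9 and 6 adjusted over the list alone (adjusted p = 0.0112; adjusted p = 0.307 with an estimated correlation). SERPINE1 rose from 275 ± 14.7 to 721 ± 22.5 CPM, and MMP1, a collagenase, rose (log2 fold change 2.07). Of 26 angiogenic factors and inhibitors, 8 rose, 5 fell and 13 did not pass, also 8 and 5 adjusted over the list alone (adjusted p = 0.0222; adjusted p = 0.146 with an estimated correlation), with FGF1 and CXCL8 among the rises. Beside these, markers of other cell types moved in MDA-MB-231. All 3 measured fibroblast and adipocyte markers rose, LUM (log2 fold change 1.92), COL1A1 (0.42) and MFAP5 (76 counts against 1). The endothelial markers KDR (2.11) and ROBO4 (1.83) and the leukocyte markers CORO1A (1.00) and LAPTM5 (0.59) rose, and EGFL7 (-0.32) and CSF1R (-0.47) of the same lists fell.

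Further lists were called higher in MDA-MB-231. Of 24 YAP/TAZ targets, 11 rose, 4 fell and 9 did not pass, or 11 and 5 adjusted over the list alone (adjusted p = 0.000821; adjusted p = 0.172 with an estimated correlation). F3, the coagulation initiator tissue factor, rose from 342 ± 23.1 to 676 ± 17.6 CPM. Of 27 epithelial genes, 8 rose, 6 fell and 13 did not pass, or 9 and 7 adjusted over the list alone (adjusted p = 0.0271; adjusted p = 0.149 with an estimated correlation), and DESeq2 test statistics did not give this call (adjusted p = 0.0839). CLDN1 rose from 1.04 ± 0.123 to 21.8 ± 0.237 CPM and SPINT1, a membrane protease inhibitor, from 17.2 ± 0.935 to 73.8 ± 1.27 CPM. Of 21 basal and myoepithelial genes, 9 rose, 2 fell and 10 did not pass, the same counts adjusted over the list alone (adjusted p = 0.00114; adjusted p = 0.159 with an estimated correlation). KRT17, a basal keratin, rose at a low level, 2.57 ± 0.853 CPM, and its reads can be shared with related keratin genes. Of 40 mitosis and G2/M genes, 31 rose, none fell and 9 did not pass, or 34 rose adjusted over the list alone (adjusted p = 9.79e-11; adjusted p = 0.0856 with an estimated correlation). CDK1, the mitotic kinase, rose from 108 ± 7.74 to 177 ± 7.23 CPM and KIF4A, a mitotic kinesin, with a log2 fold change of 0.65.

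Lipid synthesis genes were called lower in MDA-MB-231. Of 32 cholesterol and fatty acid synthesis genes, 1 rose, 23 fell and 8 did not pass, the same counts adjusted over the list alone (adjusted p = 1.20e-18; adjusted p = 0.0307 with an estimated correlation). INSIG1, a sterol sensor, fell from 204 ± 11.8 to 90.7 ± 9.49 CPM and FADS2 fell with a log2 fold change of -1.05 ± 0.07 SE. Of 32 hypoxia and glycolysis genes, 1 rose, 26 fell and 5 did not pass, also 1 and 26 adjusted over the list alone (adjusted p = 8.60e-12; adjusted p = 0.0679 with an estimated correlation). CA9, a hypoxia-induced carbonic anhydrase, fell from 6.68 ± 0.966 to 1.57 ± 0.412 CPM, and ADM, the vasodilator adrenomedullin, was the rise, from 16.2 ± 2.24 to 49.2 ± 0.933 CPM. Of 41 ribosomal protein genes, 28 fell, none rose and 13 did not pass, or 33 fell adjusted over the list alone, with a median of -0.24 (adjusted p = 6.10e-07; adjusted p = 0.307 with an estimated correlation). RPL3 fell from 1542 ± 75.4 to 1186 ± 34.9 CPM. Of 41 nuclear-encoded oxidative phosphorylation genes, 7 fell, none rose and 34 did not pass, also 7 adjusted over the list alone (adjusted p = 0.0222; adjusted p = 0.429 with an estimated correlation), with NDUFS6 at a log2 fold change of -0.41. That call ended without control replicate 3 (adjusted p = 0.0618) or LBH siRNA replicate 2 (0.101).

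Of 19 luminal and estrogen receptor genes in MDA-MB-231, 1 rose, 6 fell and 12 did not pass, the same counts adjusted over the list alone (adjusted p = 0.00823; adjusted p = 0.181 with an estimated correlation). SPDEF, an epithelial transcription factor, fell from 16.6 ± 2.25 to 4.58 ± 0.957 CPM, and the list was not called with all 24 libraries in 1 model (adjusted p = 0.0592). Of 26 ABC transporter and drug metabolism genes, 5 rose, 9 fell and 12 did not pass, the same counts adjusted over the list alone (adjusted p = 0.00100; adjusted p = 0.115 with an estimated correlation). AKR1C1 and AKR1C2, close relatives whose reads can be shared, fell with log2 fold changes of -1.80 and -1.55, and CYP1A1 rose (2.29). PSG7 and PSG6, also close relatives, had the largest rises among the named genes, from 0.0937 and 0.103 CPM to 8.81 ± 1.21 and 6.62 ± 1.73 CPM. POLA1, the catalytic subunit of DNA polymerase alpha, fell from 40.8 ± 4.80 to 10.7 ± 1.94 CPM. Of all genes called, 51.7% rose, against 61.7% with total count scaling and 43.6% with exon length offsets. With an estimated correlation, 5 of the 17 list calls held. Splits that mixed the labels gave up to 9 list calls with the preset correlation.

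**Figure D2:**
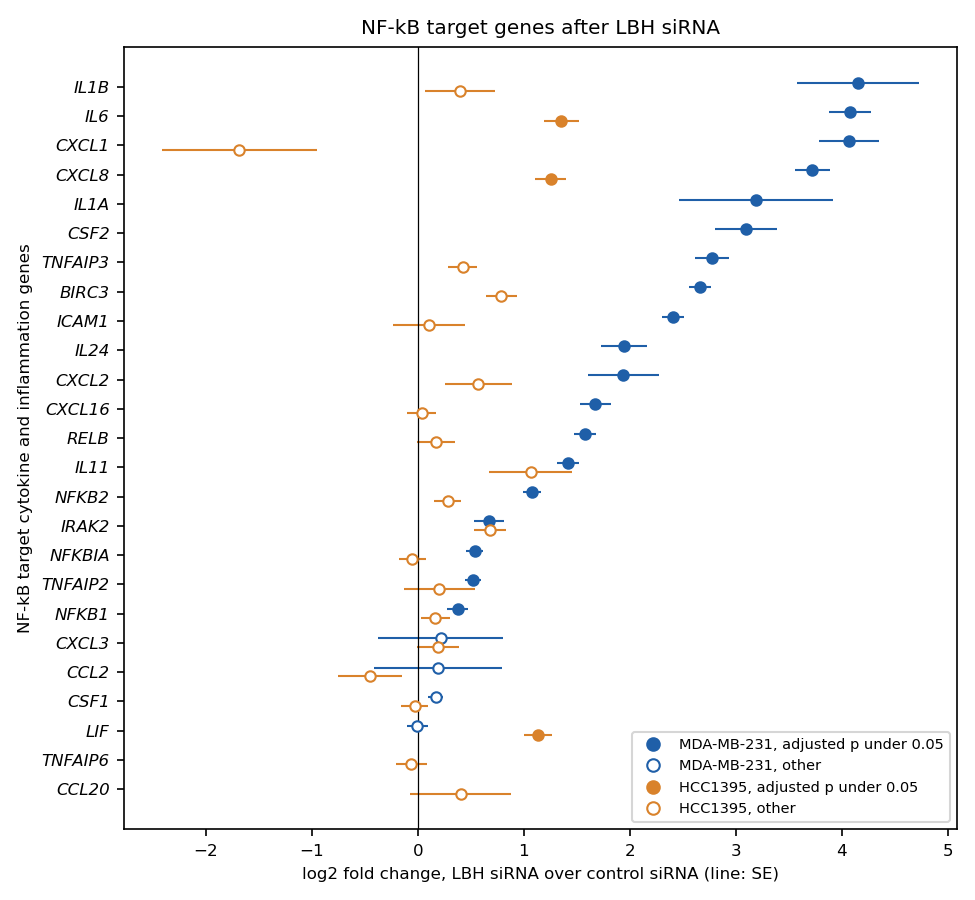
Log2 fold change (horizontal axis, line for SE) of each measured NF-kB target cytokine and inflammation gene after LBH siRNA in MDA-MB-231 (blue) and HCC1395 (orange), filled where the adjusted p was under 0.05. In MDA-MB-231 19 of 23 genes rose, and in HCC1395 3 of 22 rose.

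The HCC1395 comparison asked the same question in another triple negative line. The cytokine genes IL6, CXCL8 and LIF, the ETS factor genes ETV4 and ETV5 and the feedback gene SPRY4 rose, while PODNL1, MATN2 and CFI were among the falls. CXCL8 rose from 10.6 ± 1.31 to 25.1 ± 2.33 CPM (SD, n = 3; 2.38-fold, adjusted p = 0.0261), and IL6 from 3.38 ± 0.152 to 8.64 ± 0.411 CPM (log2 fold change 1.35 ± 0.17 SE, adjusted p = 0.0261). ETV4 and ETV5, ETS transcription factors, rose from 11.6 ± 2.62 to 27.4 ± 2.16 CPM and from 14.8 ± 2.53 to 32.4 ± 3.06 CPM, and SPRY4, a feedback inhibitor of receptor signalling, rose from 0.784 ± 0.173 to 3.43 ± 0.280 CPM. PODNL1, a leucine-rich matrix protein, fell from 51.7 ± 9.76 to 18.6 ± 0.398 CPM (log2 fold change -1.47 ± 0.16 SE, adjusted p = 0.0261). Of 15229 genes tested, 11 rose and 8 fell, and 1677 had an unadjusted p under 0.05.

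The other rises named in HCC1395 were XDH, xanthine dehydrogenase, with a log2 fold change of 1.52, TFPI2, a protease inhibitor, and LIF, a cytokine, both at 1.14, CDCP1, a transmembrane protein, at 1.06, and CPA4, a carboxypeptidase, at 0.82. The falls included PLEKHS1 (-1.31), EXTL1 (-1.14), CHI3L1, a secreted glycoprotein (-1.06), MAF, a transcription factor (-1.05), CFI, a complement regulator (-0.88), MATN2, a matrix protein (-0.85), and LGR6, a receptor for R-spondins (-0.80). These calls depended on single libraries. EdgeR called 3605 genes without control replicate 3, 13 without control replicate 2, and 0 without control replicate 1 or without LBH siRNA replicate 1, 2 or 3, where DESeq2 called 42, 38, 24 and 30 and unadjusted p was under 0.05 for 1080, 1139, 832 and 807 genes. With all 6 libraries DESeq2 called 152 genes, 65 higher and 87 lower. EdgeR called 410 with the replicate number as a block, 417 with no low count filter and 814 with all 24 libraries in 1 model, against 10 with total count scaling and 59 with exon length offsets.

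Camera called cell cycle lists higher in HCC1395. With the preset correlation, however, splits that mixed the labels gave up to 8 list calls in this line, against 10 for the real grouping. Across genes, which are not independent replicates, the HCC1395 changes had a Spearman correlation of 0.29 with exon length. The deviations of control replicates 1, 2 and 3 correlated with exon length at -0.326, -0.374 and 0.367, and those of the LBH siRNA libraries at 0, 0.213 and 0.328. For DNA replication and S phase genes, edgeR called none of 40, 17 had an unadjusted p under 0.05, all 17 higher, DESeq2 called 2, and 3 rose adjusted over the list alone. The list median was 0.26 (adjusted p = 5.54e-11; adjusted p = 0.0525 with an estimated correlation). For mitosis and G2/M genes, edgeR called none of 40, 8 had an unadjusted p under 0.05, all 8 higher, DESeq2 called 1, and 1 rose adjusted over the list alone, with a median of 0.23 (adjusted p = 1.62e-07; adjusted p = 0.0525 with an estimated correlation). With exon length offsets, the medians of these 2 lists were 0.252 and 0.249 (camera adjusted p = 9.26e-14 and 1.65e-10, preset correlation). This argues against the length trend as the source of the 2 calls. NF-kB target genes were called higher with 3 of 22 rising and 19 not passing, or 6 rising adjusted over the list alone (adjusted p = 1.36e-08; adjusted p = 0.0525 with an estimated correlation), and IL6, CXCL8 and LIF were the 3. Immediate early genes were called higher with SPRY4 rising and 29 of 30 not passing, or 7 rising adjusted over the list alone (adjusted p = 4.09e-08; adjusted p = 0.122 with an estimated correlation). For YAP/TAZ targets, edgeR called none of 22, 4 had an unadjusted p under 0.05, DESeq2 called 1, and 2 rose adjusted over the list alone (adjusted p = 0.00948; adjusted p = 0.380 with an estimated correlation). For growth factor ligands and receptors, edgeR called none of 22, 8 had an unadjusted p under 0.05, DESeq2 called 2, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.0347; adjusted p = 0.380 with an estimated correlation). Without control replicate 2 the YAP/TAZ call ended (adjusted p = 0.0642), and without control replicate 3 the growth factor call ended (0.0606). The growth factor call also ended with no low count filter (adjusted p = 0.0588), all 24 libraries in 1 model (0.108), exon length offsets (0.134) and DESeq2 test statistics (0.0624).

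Camera called ribosomal protein genes lower in HCC1395. For these 41 genes, edgeR called none, 37 had an unadjusted p under 0.05, all 37 lower, DESeq2 called 2, and 35 fell adjusted over the list alone, with a median of -0.57 (adjusted p = 9.43e-21; adjusted p = 0.384 with an estimated correlation). For 41 nuclear-encoded oxidative phosphorylation genes, edgeR called none, 8 had an unadjusted p under 0.05, DESeq2 called 0, and none passed adjusted over the list alone, with a median of -0.28 (adjusted p = 1.07e-06; adjusted p = 0.489 with an estimated correlation). The control libraries differed among themselves, with mean ribosomal deviations from the line average of 0.34, 0.66 and -0.22 on the log2 scale for control replicates 1, 2 and 3, against -0.14, -0.25 and -0.39 for the LBH siRNA libraries. For 21 antigen presentation genes, edgeR called none, 6 had an unadjusted p under 0.05, DESeq2 called 2, and 2 fell adjusted over the list alone (adjusted p = 0.00119; adjusted p = 0.384 with an estimated correlation). For 9 fibroblast and adipocyte markers, edgeR called none, 6 had an unadjusted p under 0.05, DESeq2 called 2, and 5 fell adjusted over the list alone (adjusted p = 0.00261; adjusted p = 0.142 with an estimated correlation).

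**Figure D3:**
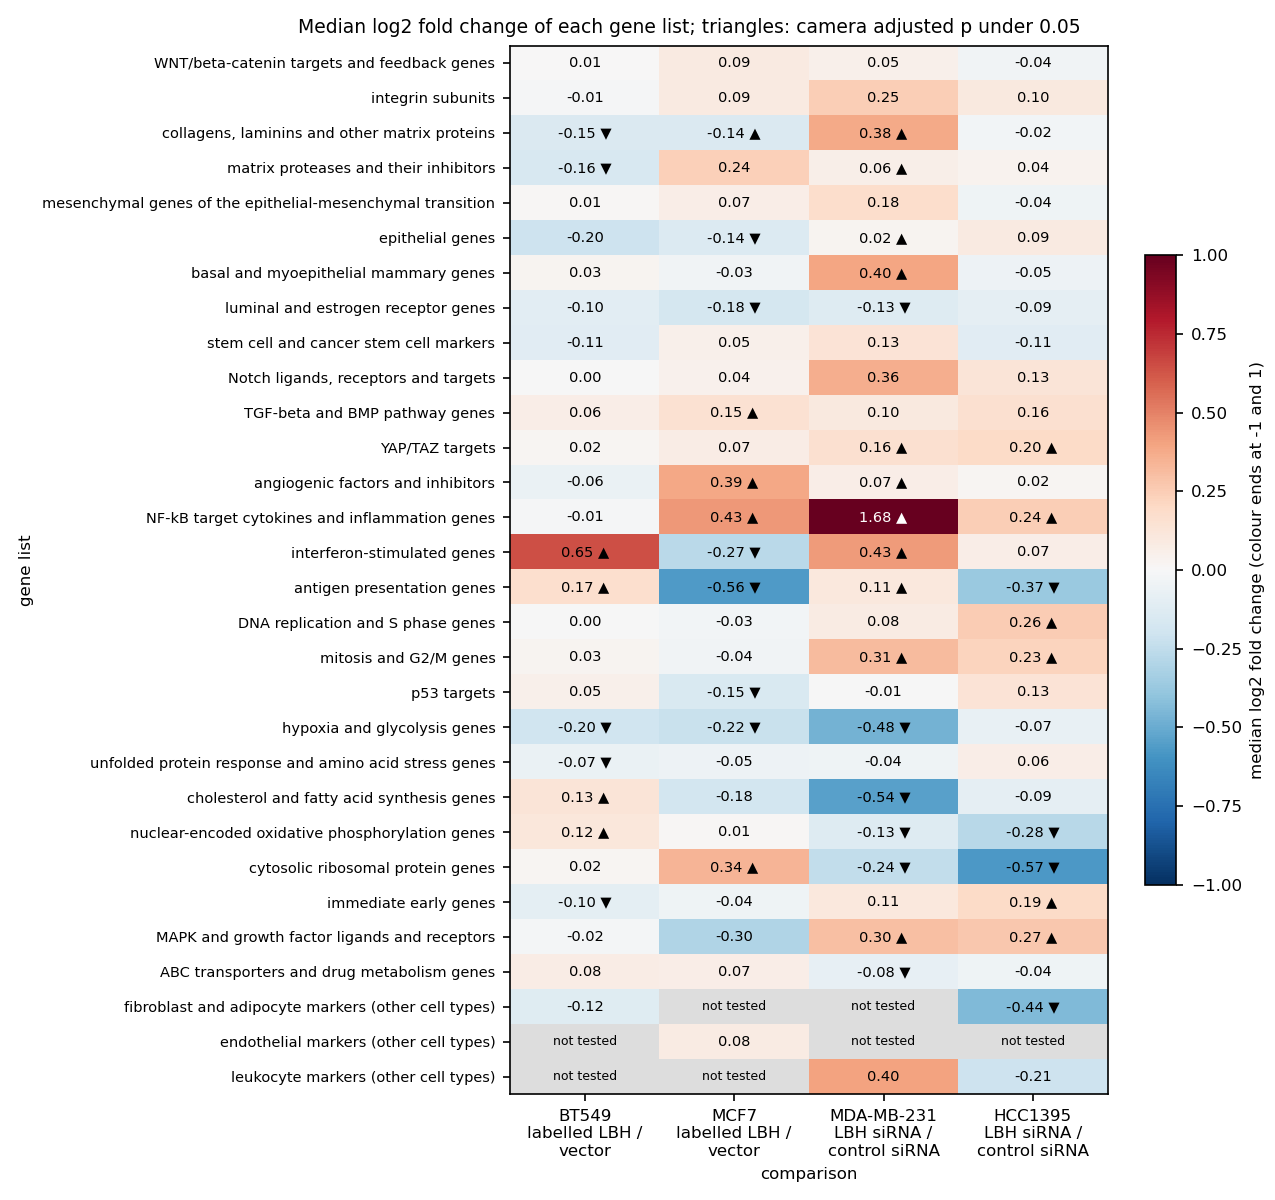
Median log2 fold change (colour and number) of the measured members of each fixed gene list (vertical axis) in the 4 comparisons (horizontal axis), with triangles for the direction of lists called by camera with the preset correlation. The largest median was 1.68 for NF-kB target genes in MDA-MB-231, and grey fields had fewer than 5 tested members.

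Camera did not call WNT/beta-catenin targets and feedback genes as a list in any line, whereas fry called them in MCF7 (adjusted p = 0.0374). Fry called 22 of the 28 lists tested in MCF7, so its WNT call does not single out this list. In BT549, 2 of 14 rose and 1 fell (adjusted p = 0.315), with TNFRSF19 and DKK1 up and NOTUM, an extracellular WNT inhibitor, down. In MCF7, 3 of 17 rose and none fell (adjusted p = 0.526), among them AXIN2, a feedback inhibitor of the pathway, with a log2 fold change of 0.50. In MDA-MB-231, 2 of 15 rose and 2 fell (adjusted p = 0.743), and in HCC1395 LGR6 was the only call of 18 (adjusted p = 0.522).

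Whether the overexpression labels went with the same changes in BT549 and MCF7 was tested as an interaction. Camera called interferon-stimulated and antigen presentation genes higher in BT549 and lower in MCF7, although no such call within a line held with an estimated correlation (adjusted p = 0.129 and 0.523 in BT549, 0.329 and 0.180 in MCF7). The median differences, BT549 minus MCF7, were 1.05 (adjusted p = 2.45e-13; adjusted p = 0.0379 with an estimated correlation) and 0.83 (adjusted p = 9.53e-07; adjusted p = 0.0383 with an estimated correlation). Genes that rose in both lines by the largest smaller fold were STRA6, KYNU, PLPPR3, TRNP1 and IFITM3, and those that fell in both were NDRG1, NR4A2, SLC16A3, PDK1 and COL6A2. SLC16A3, a lactate exporter, had log2 fold changes of -0.97 and -0.88, and IFITM3, an interferon-induced membrane protein, 0.69 and 0.65, without a difference past the test (adjusted p = 0.803 and 0.804). Of 17130 genes, 3203 had effects that differed between the lines, or 1561 with all 24 libraries in 1 model, and 11 of 29 lists differed, 4 of them with an estimated correlation.

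Among genes tested in both lines, 594 were called in BT549 and 5046 in MCF7, and 332 in both. Of these, 190 moved in the same direction against 113.4 expected by independent draws, and 142 in opposite directions against 112.9. Pearson's r across genes was 0.079 and Spearman's rho 0.103, and 28 of 100 splits of the libraries gave an absolute Pearson correlation as large, so the correlation was not beyond chance. Genes are not independent replicates. The count of 190 was 111, 104 or 97 without BT549 vector replicate 1, 2 or 3, 78 without labelled BT549 replicate 1 and 401 without labelled BT549 replicate 3.

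After LBH siRNA, IL6, CXCL8, TFPI2, CPA4 and CDCP1 rose in both MDA-MB-231 and HCC1395, and PODNL1 fell in both. The rises were larger in MDA-MB-231 for IL6 (log2 difference 2.74 ± 0.25 SE, adjusted p = 5.04e-06), CXCL8 (2.48 ± 0.22 SE, adjusted p = 2.30e-06), CPA4 (1.07) and TFPI2 (1.06). CDCP1 rose with log2 fold changes of 0.48 and 1.06, whose difference did not pass (adjusted p = 0.0561). By list, NF-kB target genes had the higher change in MDA-MB-231, with a median difference of 1.40 (adjusted p = 5.89e-23, or 9.36e-05 with an estimated correlation). Lipid synthesis and hypoxia and glycolysis genes were lower there, with median differences of -0.47 (adjusted p = 1.24e-12; adjusted p = 0.000588 with an estimated correlation) and -0.44 (adjusted p = 4.48e-10; adjusted p = 0.0244 with an estimated correlation). Of 17027 genes, 536 had effects that differed, or 1240 with all 24 libraries in 1 model and 894 in DESeq2, and 14 of 29 lists differed, 6 of them with an estimated correlation. The gene count was 1929 without HCC1395 control replicate 3, 315, 310 or 298 without HCC1395 LBH siRNA replicate 1, 2 or 3, and 337 or 350 without MDA-MB-231 LBH siRNA replicate 1 or 2. LBH siRNA left 8.2% of the control LBH level in MDA-MB-231 and 26.8% in HCC1395. Differences between the lines therefore cannot be told apart from effects of unequal knockdown.

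Among genes tested in both knockdown lines, 3703 were called in MDA-MB-231 and 18 in HCC1395. Of the 11 called in both, 7 moved in the same direction against 2.5 expected and 4 in opposite directions against 2.5. Across genes, Pearson's r was 0.257 and Spearman's rho 0.310, and 2 of 100 splits of the libraries, the real one included, gave an absolute Pearson correlation as large. The 7 shared genes depended on HCC1395 libraries: 1043 genes moved in the same direction without HCC1395 control replicate 3. Without HCC1395 control replicate 1 or any of the 3 LBH siRNA libraries, edgeR called no HCC1395 gene, so none could be shared. DESeq2 gave 56 shared genes.

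Across all 4 lines, some genes moved 1 way with the labelled LBH status, up with overexpression and down with knockdown or the reverse. CXCL8 fell in BT549 (log2 fold change -0.99) and rose in MDA-MB-231 (3.72), and it rose 2.38-fold in HCC1395. ADM fell in BT549 (-0.56) and MCF7 (-0.96) and rose in MDA-MB-231 (1.61), and FADS2 rose in BT549 (0.49) and MCF7 (0.61) and fell in MDA-MB-231 (-1.05). SORCS2, BCAT1 and XPA followed the direction of FADS2, and CDCP1, GDF15, COL6A2 and TPD52 that of ADM in the 3 lines where each was called. Of 159 genes called in at least 3 lines, 46 followed 1 direction relative to the label, against 39.4 expected if signs were independent. In either direction, 2 genes were called in all 4 lines. SPRY4 was 1 of these and did not follow the label: it fell in BT549 (-0.47) and MDA-MB-231 (-0.55) and rose in MCF7 (0.92) and HCC1395 (2.14). LBH reads did not rise in BT549 or MCF7, so all directions relative to LBH status rest on the labels. Hypoxia and glycolysis genes did not follow the label as a list. They were called lower in BT549, MCF7 and MDA-MB-231 alike, with 10, 17 and 26 members falling. None of these 3 calls held with an estimated correlation (adjusted p = 0.134, 0.329 and 0.0679).

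**Figure D4:**
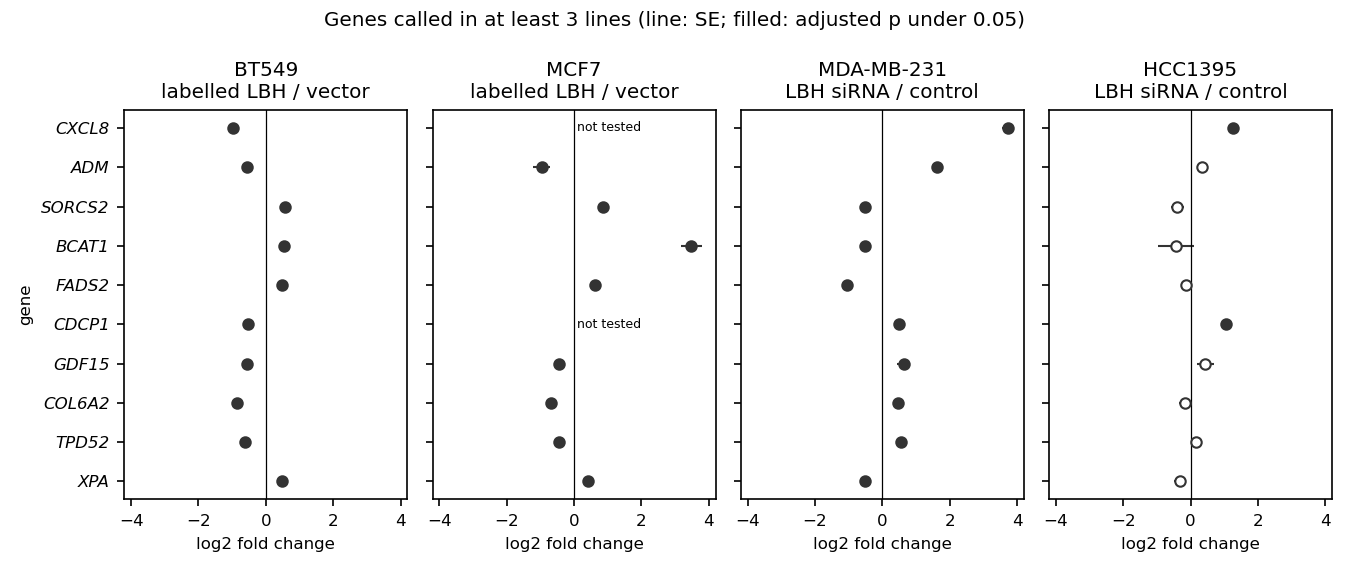
Log2 fold change (horizontal axis, line for SE) of the 10 genes called in at least 3 lines with 1 direction relative to the labelled LBH status, filled where the adjusted p was under 0.05. CXCL8 ranged from -0.99 in BT549 to 3.72 in MDA-MB-231.

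Between lines with opposite manipulations, calls overlapped in both directions. For BT549 and MDA-MB-231, 151 of 309 shared calls had opposite signs against 86.6 expected, and 158 the same sign against 86.5. For MCF7 and MDA-MB-231, 1004 of 1705 had opposite signs against 698.4 expected, and 701 the same sign against 697.9. With HCC1395, 5 of 5 calls shared with BT549 and 3 of 5 shared with MCF7 had opposite signs. Pearson's r across genes was -0.002, -0.035, -0.143 and -0.141 for these pairs, with Spearman's rho of -0.026, -0.085, -0.186 and -0.179, and 94, 31, 35 and 29 of 100 splits gave an absolute Pearson correlation as large. The 151 genes were 81, 72 or 72 without BT549 vector replicate 1, 2 or 3, 57 without labelled BT549 replicate 1 and 276 without labelled BT549 replicate 3. The counts of 5 and 3 were 170 and 1092 without HCC1395 control replicate 3, and no gene could be shared where edgeR called none in HCC1395.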

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

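The tests of LBH reads against the labels, of block-wise shifts along the chromosomes, of exon length in MCF7 and of control replicate 3 in HCC1395 were chosen only after the result was seen. The genes and lists given first in this part stood out because an effect differed between 2 lines by the interaction test. That test covered 17130 genes for BT549 and MCF7 and 17027 for MDA-MB-231 and HCC1395. Only 13247 and 13267 genes were tested in both lines alone, so the rest were too low for that in at least 1 line. The patterns of LBH reads, of MCF7 windows and of HCC1395 ribosomal genes were noticed within lines, without that test.

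Between BT549 and MCF7, as BT549 minus MCF7 on the log2 scale, the effects differed for BCAT1 (-2.91), PLPPR3 (-0.50), NDRG1 (0.86), TFPI2 (0.56) and CPA4 (-1.74). CPA4 changed by -0.13 in BT549 without passing and was too low in MCF7 to be tested there alone. Of the genes named within a line, 37 named in BT549 and 72 named in MCF7 differed. The lists whose effects differed upward by camera were interferon-stimulated genes (median difference 1.05), antigen presentation genes (0.83), cholesterol and fatty acid synthesis genes (0.28), p53 targets (0.14) and mitosis and G2/M genes (0.07). Those that differed downward were angiogenic factors and inhibitors (-0.61), ribosomal protein genes (-0.32), NF-kB target genes (-0.18) and TGF-beta and BMP pathway genes (-0.17). Matrix protein genes and fibroblast and adipocyte markers were called downward although their medians were 0.10 and 0.35. With an estimated correlation, 4 calls held: interferon-stimulated genes (adjusted p = 0.0379), antigen presentation genes (0.0383), TGF-beta and BMP pathway genes (0.0379) and angiogenic factors and inhibitors (0.0379).

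Between MDA-MB-231 and HCC1395, as MDA-MB-231 minus HCC1395, the effects differed for LBH (-1.70), IL6 (2.74), CXCL8 (2.48), TRNP1 (1.73), ADM (1.27), CPA4 (1.07), TFPI2 (1.06), FADS2 (-0.90) and NDRG1 (-0.74). Since the LBH effect itself differed, the other differences cannot be told apart from effects of unequal knockdown. Of the genes named within a line, 40 named in MDA-MB-231 and 10 named in HCC1395 differed. The lists whose effects differed upward were fibroblast and adipocyte markers (median difference 1.62), NF-kB target genes (1.40), basal and myoepithelial genes (0.66), antigen presentation genes (0.43), interferon-stimulated genes (0.38), mesenchymal genes (0.38), ribosomal protein genes (0.35), matrix protein genes (0.29) and mitosis and G2/M genes (0.14). Those that differed downward were cholesterol and fatty acid synthesis genes (-0.47), hypoxia and glycolysis genes (-0.44), DNA replication and S phase genes (-0.16), ABC transporter and drug metabolism genes (-0.12) and unfolded protein response genes (-0.05). With an estimated correlation, 6 held: NF-kB target genes (adjusted p = 9.36e-05), cholesterol and fatty acid synthesis genes (0.000588), mesenchymal genes (0.0244), hypoxia and glycolysis genes (0.0244), fibroblast and adipocyte markers (0.0259) and ABC transporter and drug metabolism genes (0.0396).

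Splits of the libraries within both lines at once were drawn 100 times of 200 possible, the real grouping included. For BT549 and MCF7, 3 of 100 gave as many genes as the real 3203, with 3574 the highest other. For MDA-MB-231 and HCC1395, 4 of 100 gave as many as the real 536, with 3642 the highest other. All the other splits that gave as many kept the real grouping of at least 1 line, so they hold that line's effect and are not random groupings. The splits with the real grouping of neither line, 82 and 86 in number, called 0 genes in edgeR. Among the other 99 splits, the exact 95% interval (Clopper-Pearson) of the share as large was 0.246% to 7.11% for the first pair and 0.629% to 8.6% for the other. The shares are under 0.05, but they count splits that are not random groupings, the intervals reach above 0.05 and a smaller earlier draw had put the shares at or above it, so these splits do not settle whether chance is excluded. For the knockdown pair, the 3 splits above the real count, with 3642, 2150 and 1167 genes, kept the grouping of MDA-MB-231 and set 2 or 3 HCC1395 LBH siRNA libraries beside its controls. Their counts can follow from the effects of the 2 lines, which such splits add. The split with 3642 genes set HCC1395 control replicate 3 beside LBH siRNA replicates 2 and 3, and a split with control replicate 2 in its place called 498. This points to a structure of the samples, with control replicate 3 apart from control replicate 2, whose cause was not tested here.

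LBH reads were not higher in the libraries labelled LBH overexpression. The LBH log2 fold change of -1.29 in BT549, and a sum of 1 count over the 3 labelled MCF7 libraries, restate this pattern and test no explanation of it. Exchanged group columns in BT549 stay open, since the correlation of its changes with those of MDA-MB-231 across genes was -0.002, near neither sign. A candidate explanation that the counts cannot test is an insert whose reads were not counted as human LBH, since the labels write it as Lbh and do not state its species. A change of the cells' own LBH after overexpression also stays open, as untested.

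Neighbouring genes moved together between the 2 sets of MCF7 stable transfectants. In 15 windows of 10 Mb the median change lay beyond the 95th percentile of permuted positions, against at most 2 in a knockdown line and 3 in BT549, the other stably transfected line. Block-wise shifts along the chromosomes, such as copy number differences between cell populations, would give such windows. With the window medians removed, 4525 genes were called and 3730 of the 5760 calls, 64.8%, stayed, while medians of permuted positions left 5860 to 5963 calls, so how much of the MCF7 result such shifts could account for cannot be told apart from an effect of the labelled LBH status. After exon length offsets 92.1% of the calls were shared, which argues against a length trend. In BT549, 568 of the 746 calls, 76.1%, stayed with the window medians removed, while medians of permuted positions left 746 to 809 calls. The BT549 window of chromosome 5 from 70 to 80 Mb, which holds IQGAP2, had 6 falls, no rise and a median of -0.17. In MDA-MB-231, which was not stably transfected, 85.7% stayed. LBH status and transfectant population coincide in MCF7 and in BT549, and the biological explanation stays open as untested.

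By list median, ribosomal protein and oxidative phosphorylation genes were lower in the HCC1395 LBH siRNA libraries. EdgeR called none of the 41 members of either list. Neither list call held with an estimated correlation (adjusted p = 0.384 and 0.489). Exon length offsets left 86.4% of the ribosomal median, which went from -0.57 to -0.50, and GC offsets left 100%, so neither trend was the whole cause. Control replicate 3 had ribosomal levels near the LBH siRNA libraries (-0.22 against 0.34 and 0.66 in the other controls). Its oxidative phosphorylation level, -0.22, was the lowest, against 0.18 and 0.45 in the other controls and -0.04, -0.15 and -0.21 in the LBH siRNA libraries. The LBH level of control replicate 3, 11.9 CPM, argues against an LBH siRNA library under a control label. A difference in RNA handling among the control libraries and an effect of LBH siRNA may both contribute and were not tested further.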

How the results depend on the processing

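Total count scaling, exon length offsets, GC offsets, window medians and the alternatives for list differences were chosen after the data were seen. No result that passed its test was reversed under any alternative run. Of the comparisons of named genes with their alternatives, 1030 of 1170 kept their side of the threshold in BT549, 1436 of 1467 in MCF7, 1420 of 1469 in MDA-MB-231 and 360 of 454 in HCC1395. For lists the numbers were 394 of 420, 391 of 420, 393 of 420 and 399 of 435, and for differences between lines 751 of 799. Named genes of a line include some called only in other lines, which kept their side by staying uncalled. The 210 HCC1395 comparisons of named genes that left out 1 library include such genes, and the call ended in 78. For the changes below, the cause was not tested, except that a fold threshold or fewer libraries can by construction lower a count. With a fold threshold of log2 1, 92 genes remained in BT549, 853 in MCF7 and 673 in MDA-MB-231. With all 24 libraries in 1 model, counts were 273 in BT549, 3682 in MCF7 and 814 in HCC1395, and 1561 genes differed between BT549 and MCF7 and 1240 between MDA-MB-231 and HCC1395. With an estimated correlation, the called lists numbered 0 in BT549, 0 in MCF7, 5 in MDA-MB-231 and 0 in HCC1395, and the lists that differed 4 and 6 for the overexpression and knockdown pairs; fry called 7, 22, 22 and 5 in the 4 lines.

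In HCC1395, where edgeR called 19 genes, it called 417 with no low count filter, 410 with the replicate block, 10 with total count scaling, which shifted the median of all genes by 0.103, and 59 with exon length offsets, and DESeq2 called 152. LBH in HCC1395 passed with no filter (-1.90, adjusted p = 5.22e-12), all 24 libraries (-1.90, adjusted p = 3.29e-05), the block (-1.84, adjusted p = 6.38e-06), exon length offsets (-1.90, adjusted p = 0.0199) and DESeq2 (-1.89, adjusted p = 1.41e-05). DESeq2 called 894 genes that differed between the knockdown lines. Correlations of like-numbered libraries were between -0.15 and 0.10 in the other lines, and 0.08, 0.04 and 0.35 for HCC1395 replicates 1, 2 and 3. They showed no general pairing by replicate number. A shared replicate effect in HCC1395 stays open, since the block raised its count from 19 to 410. Of the MDA-MB-231 calls, 51.7% rose, against 61.7% with total count scaling and 43.6% with exon length offsets.

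Without each library in turn, counts ranged from 318 (without labelled BT549 replicate 1) to 1362 (without labelled BT549 replicate 3) in BT549, 4063 to 7035 in MCF7, 2950 to 3826 in MDA-MB-231, and in HCC1395 from 0, without control replicate 1 or any LBH siRNA replicate, to 3605 without control replicate 3. For these 4 settings with 0 edgeR calls, 1080, 1139, 832 and 807 genes had an unadjusted p under 0.05 and DESeq2 called 42, 38, 24 and 30. LBH in HCC1395 ranged from -2.16 to -1.61, and the genes that differed between the knockdown lines from 298 to 1929, the extremes being without LBH siRNA replicate 3 and control replicate 3 of HCC1395.

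Shared genes in the direction tested, for BT549 and MCF7, numbered 290 with no filter, 60 with all 24 libraries, 6 with the fold threshold, and 78 to 401 without each library. For MDA-MB-231 and HCC1395 they numbered 158 with no filter, 56 with DESeq2, 296 with all 24 libraries, 146 with the block, 4 with the fold threshold, and 0 to 1043 without each library. For BT549 and MDA-MB-231 the numbers were 52 with all 24 libraries, 4 with the fold threshold and 57 to 276. For BT549 and HCC1395 they were 62 with no filter, 25 with DESeq2, 37 with all 24 libraries, 37 with the block, 0 with the fold threshold, and 0 to 170. For MCF7 and MDA-MB-231 they were 668 with all 24 libraries and 29 with the fold threshold. For MCF7 and HCC1395 they were 154 with no filter, 40 with DESeq2, 201 with all 24 libraries, 128 with the block, 1 with the fold threshold, and 0 to 1092. LBH in MCF7 had 1 count per group, too few for any value fitted under the alternatives to be informative. At 14181372 to 23636019 counts per library, these counts lay under the floor of 3 counts over the group.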

Other observations

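The test of ERK output genes was written before its values in MDA-MB-231 were seen, but its genes were chosen after SPRY4, ETV4 and ETV5 had been seen to rise in HCC1395, and the chromosome windows were looked at after the data were seen.

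Single genes of cell adhesion and cell state changed in MCF7 in lists that camera did not call, in a line where 36.7% of all tested genes were called. Fry called the integrin (adjusted p = 0.0360), basal (0.0348) and stem cell (0.0147) lists, and did not call the mesenchymal list. It called 22 of the 28 lists tested in MCF7, so its calls do not single out these lists. Of 17 integrin subunit genes, 4 rose and 7 fell (adjusted p = 0.777), with ITGAM (log2 fold change 2.68) and ITGB8 (1.37) up and ITGA5, the fibronectin receptor subunit, down (-1.35). Of 18 basal and myoepithelial genes, 5 rose and 4 fell (adjusted p = 0.354), with a median of -0.03 but a mean of 0.28. TP63, a transcription factor of basal epithelial cells, rose from 0.185 ± 0.117 to 4.30 ± 0.234 CPM (SD, n = 3). Of 13 mesenchymal genes, 2 rose and 2 fell (adjusted p = 0.809), and the rises were the transcription factors SNAI2 (log2 fold change 1.66) and TWIST1, the latter at 0.719 CPM. Of 19 stem cell markers, 5 rose and 5 fell (adjusted p = 0.681), with SOX2 up (0.93) and CD44, a hyaluronan receptor, down (-1.11).

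In MDA-MB-231, 6 of 18 mesenchymal genes rose and 4 fell (adjusted p = 0.119), with CDH2, the adhesion protein N-cadherin, rising from 0.513 ± 0.408 to 4.13 ± 0.471 CPM and S100A4 falling (log2 fold change -0.97). Of 25 TGF-beta and BMP pathway genes, 9 rose and 5 fell (adjusted p = 0.192). INHBA, an activin subunit, rose with a log2 fold change of 3.40 ± 0.25 SE, and ID1, a BMP target, fell from 484 ± 22.5 to 220 ± 19.8 CPM. Of 15 Notch pathway genes, 5 rose and 1 fell (adjusted p = 0.0953), with the ligands JAG1 and JAG2 up. Fry called these 3 lists (adjusted p = 0.0135, 0.00959 and 0.00176), but it called 22 of the 28 lists tested in this line, where 27.6% of all tested genes were called. On chromosome 19 from 20 to 30 Mb, 14 of 40 tested genes rose and none fell, with a median log2 fold change of 0.51.

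A hypothesis was that LBH siRNA raises ERK output genes in both knockdown lines, tested on a list of 10 such genes, 5 of which the immediate early list also holds. In MDA-MB-231 the list was lower, not higher (camera p = 0.0167, or p = 0.196 with an estimated correlation), with 1 gene rising and 6 falling, so the hypothesis did not hold there. In HCC1395 the 7 genes other than SPRY4, ETV4 and ETV5 were higher (camera p = 2.84e-11, or p = 0.00237 with an estimated correlation), with 6 of 7 above 0, which may reflect a response of that line alone. In BT549 the list was lower (camera p = 2.42e-05, or p = 0.0285 with an estimated correlation), and so were its 7 other genes (p = 0.0310, or p = 0.136 with an estimated correlation). In MDA-MB-231 those 7 genes gave p = 0.0438, or p = 0.274 with an estimated correlation. Of the 10 genes in MCF7, 4 rose and 4 fell.

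Splits of the 6 libraries of a line into 3 and 3 number 10, too few for a share under 0.05. The real grouping was the 1 split of 10 with as many calls in each line. It gave 746 genes in BT549, 5760 in MCF7, 4088 in MDA-MB-231 and 19 in HCC1395, and the highest other split gave 1, 0, 0 and 0. It gave 9, 11, 17 and 10 lists, and the highest other split gave 8, 8, 9 and 8. Camera with the preset correlation thus also called lists where the labels were mixed, in BT549 and HCC1395 nearly as many as in the real grouping. A list call at that setting alone is therefore weak evidence of a change with the label.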
